A study of Mus musculus with 12 samples.

How the data were processed

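The series holds 12 Smart-seq2 RNA-seq libraries of mouse embryos and ES cells, and its title calls the measurement single cell RNA-seq. Groups and replicate numbers were taken from the sample labels, which give the strain and genotype of each sample. The deposited files list, per gene, an FPKM, a TPM and a coverage value for each library. Per the submitters' processing notes the tools were STAR, listed with the version 0.6.0, StringTie and DESeq2, and the build was mm9. The roles and settings of these tools and the annotation are not given in the sources used here. FPKM is a read count per length of gene and per amount of reads, so the deposited FPKM values hold no counts and no count model was used.

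The deposited TPM values are the FPKM values multiplied by 1 factor per library, 1.78 to 2.93, so that each library has the same sum, and they served as an alternative scaling. The deposited coverage value divided by FPKM was the same, within 1%, for 88.4% to 89.0% of genes of a library. That ratio, from 0.373 to 2.01, gives the relative depth of the libraries but not their number of reads, so no counting interval could be given. The rows without a gene name, 227 to 339 per library and 0.549% to 1.19% of FPKM, were left out of the tests. The values of the 46 or 47 symbols listed at more than 1 locus were summed, which left 22619 symbols. Mitochondrially encoded genes were fixed as a list, and no member was found among the symbols. Read strand is not stated, so overlapping genes on opposite strands cannot be told apart, and near-identical copies (Zscan4, Omt2, Tcl1b, Usp17l and Gm2016 families, ribosomal protein and respiratory chain genes with copies) share reads in a way the values do not show.

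KO embryo, KO arrest and control embryo were compared pairwise in 1 fit of 8 libraries (5 residual degrees of freedom), and KD ESC with control ESC in a fit of 4 libraries (2 residual degrees of freedom). The difference of the KO embryo and KD ESC effects came from a fit of all 12. Each used limma 3.58.1 in R 4.3.3, with the trend of the variance on the mean, on log2(FPKM + 1). Genes were kept with at least 1 FPKM in at least 2 libraries, and called at a Benjamini-Hochberg adjusted p under 0.05 over the genes kept. The pseudocount of 1 understates the change of low genes. Values of the Zscan4 sum were compared by exact permutation tests in scipy 1.17.1. Other tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

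The designs, the 29 gene lists, the rule for named genes and the alternatives were chosen before the data were examined. Lists with at least 4 tested members were tested by limma's camera with a preset correlation of 0.01, then with an estimated correlation, and by fry, with adjustment over the 27 lists of a comparison. With the estimated correlation no list of any comparison was called. By fry 12, 15, 11 and 8 lists were called in the 4 comparisons, in the order of the report, and these are not all the lists that camera called. A list described as called or not called without a named test refers to camera with the preset correlation. The lists cover two-cell, Zscan4, maternal oocyte, pluripotency, trophectoderm, primitive endoderm, germ layer, p53 and apoptosis, integrated stress, heat shock, telomere, homologous recombination, CUL4-DDB1 ligase, KAP1 and heterochromatin, imprinted, DNA replication, mitosis, ribosomal protein, oxidative phosphorylation, proteasome, histone, mitochondrially encoded, glycolysis, cholesterol and lysosome genes, and markers of cumulus cells, fibroblasts, blood and sex. The genes named are Dcaf11, Trim28 and the Zscan4 members in every comparison. To these come, among called genes whose libraries separate the groups, the 10 with the largest rise and the 10 with the largest fall, with the single largest predicted or systematically named gene in each direction apart, and the 4 members with the smallest p of each called list and of the lists of early genes and of other cells. Some genes that this rule picks are not reported. Symbols of the D16Ertd and C86187 type do not match that pattern and count as named.

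The correlation and covariance of fold changes that share controls were set against 100 simulated draws of unchanged groups, and overlaps of calls without shared libraries against the product of the 2 shares. Alternatives were a pseudocount of 0.1, no filter or a minimum of 5 FPKM, TPM, median-of-ratios and quantile scaling, weights per library, a log2 fold change of at least 1, other sets of libraries in the fit, the replicate number as a block, and each library left out. Where a library left out leaves 1 in its group, that library is assumed to vary like the other groups. Removal of the trend of each library with gene length, drawn through genes outside the ribosomal, oxidative phosphorylation and proteasome lists, was added after seeing the data. Lengths came from the GENCODE annotation of another build, GRCm38, matched by symbol, and 94.3% of the genes tested in each fit had a length. Lists of bone marrow, bone and connective tissue, liver, skeletal muscle and brain transcripts were also added then.

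The fits were tested on simulated data made with the real means and spreads, in which 200 genes were changed. Each gene was drawn independently, with 1 spread for all groups, so the counts below hold only for such data. A list moved as a whole was also recovered by camera in all 5, which does not test calls of lists whose genes vary together. Over 11795 genes, KO embryo against control embryo recovered 0.0% of changes of 1, 8.96% of changes of 2 and 39.4% of changes of 3 on the log2 scale, and called 1 of 11565 unchanged genes. KO arrest against control embryo recovered 1.49%, 8.96% and 59.1%, and KO arrest against KO embryo 0.0%, 13.4% and 51.5%, calling 4 and 5 of 11565 unchanged genes. KD ESC against control ESC, over 12264 genes, recovered 37.3%, 89.6% and 98.5% and called 14 of 12034. The difference, over 14447 genes, recovered 0.0%, 2.99% and 13.6% and called 0 of 14217.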

Results

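RNA from mouse embryos and mouse embryonic stem (ES) cells was sequenced as 12 Smart-seq2 libraries, a full-length cDNA method for very small amounts of RNA. The embryos were of the C57BL/6 strain and fell into 3 groups: wild type (control embryo, n = 2), Dcaf11 knockout (KO embryo, n = 3) and Dcaf11 knockout with the word arrest in the title (KO arrest, n = 3). The ES cells were of the 129Sv strain, either control (control ESC, n = 2) or with Dcaf11 knocked down (KD ESC, n = 2). Dcaf11 encodes a substrate receptor of the CUL4-DDB1 ubiquitin ligase. The labels give neither the stage nor the sex of the embryos nor how many cells went into a library. Nothing in them says that libraries of 1 group came from separate embryos or cultures, so p-values measure only the spread between these libraries, which may be technical.

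Expression was given as FPKM without read counts. The read coverage of a gene at 1 FPKM, which is proportional to depth, was 2.01 and 1.22 in the control embryos, 0.585, 0.988 and 1.32 in the KO embryos and 0.373, 0.523 and 0.659 in the KO arrest libraries. It was 0.907 and 1.08 in the control ESC and 0.566 and 0.943 in the KD ESC libraries. Between 6573 and 12061 genes reached 1 FPKM. The lowest number was that of control embryo 1, the deepest library, in which Wtap alone stood at 24385 FPKM. Across genes, which are not independent replicates, the control embryos correlated with each other at r = 0.774, the KO embryos at 0.893 to 0.919, the KO arrest libraries at 0.888 to 0.918, the control ESC pair at 0.970 and the KD ESC pair at 0.960.

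Dcaf11 (mm9 chromosome 14, 56178866 to 56188902) was examined as a possible check of the labels of the knockout and the knockdown. It stood at 2.82 and 14.3 FPKM in the control embryos, 3.99, 2.84 and 0.184 in the KO embryos and at 4.43, 0.422 and 6.02 in the KO arrest libraries. The log2 fold change, on the log2(FPKM + 1) scale used throughout, was −1.43 ± 0.95 (SE) in KO embryos against control embryos (limma, adjusted p = 0.411) and −1.02 ± 0.95 in KO arrest against control embryos (adjusted p = 0.463). Without control embryo 1 these values were −2.43 and −2.02, and without control embryo 2 they were −0.43 and −0.01. The gene did not separate knockout from control libraries. The values cover the whole gene, and the deleted part is not given in the sources used here, so the embryo values do not check the labels. In ES cells Dcaf11 was at 1.69 and 1.83 FPKM in the KD ESC libraries and at 6.48 and 4.52 in the control ESC libraries. This is a log2 fold change of −1.22 ± 0.21 with both KD ESC libraries below both controls (adjusted p = 0.0521).

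**Figure D1:**
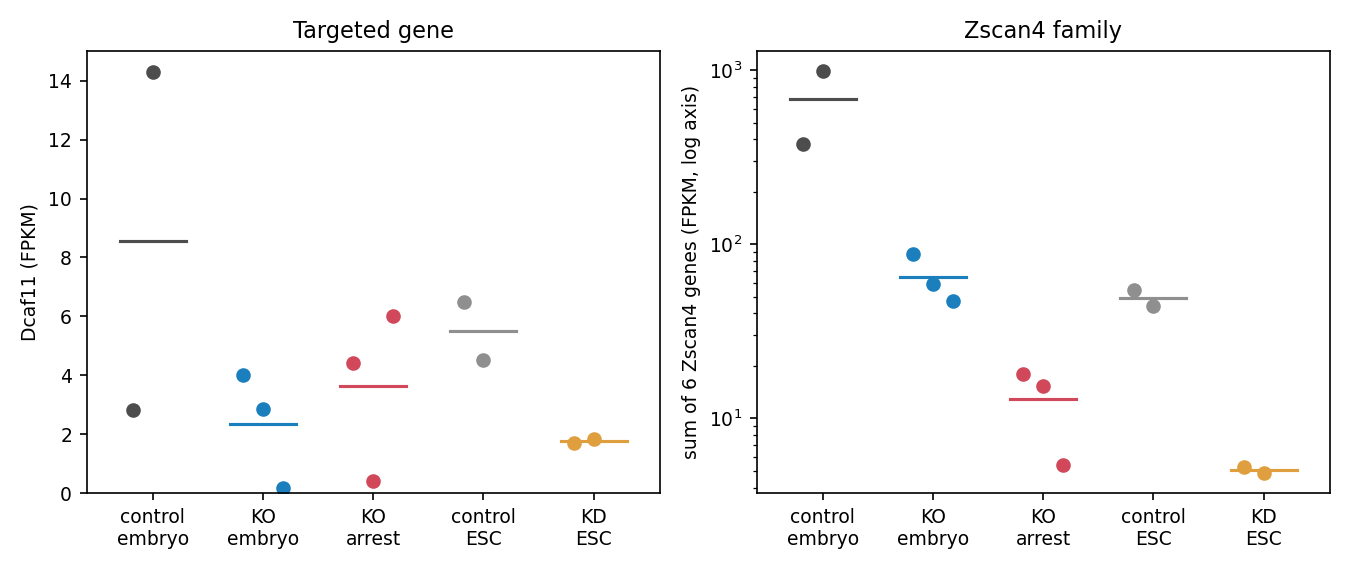
FPKM of Dcaf11 (left, linear axis) and the summed FPKM of 6 Zscan4 genes (right, log axis) in each library by group; points are libraries and bars are group means. The Zscan4 sums were 374 and 990 in the control embryos and at most 87.3 in any knockout library, and 54.2 and 44.0 in the control ESC against 5.28 and 4.84 in the KD ESC libraries.

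The comparison of KO embryos with control embryos asks which transcripts differ between embryos labelled as Dcaf11 knockout and as wild type. Zscan4 genes, SCAN zinc-finger genes expressed at the two-cell stage and linked to telomere lengthening, were lower in the KO embryos. The sum over the 6 members (mm9 chromosome 7, from Zscan4a at 11379590 to Zscan4f ending at 11987667) was 64.5 ± 20.6 FPKM (SD, n = 3) against 682 ± 436 (SD, n = 2), 10.6-fold lower (5.80-fold without control embryo 2). Of 40 oocyte genes 8 fell, among them the abundant Omt2b (9163 ± 1806 against 23905 ± 4477 FPKM) and Omt2a (5822 ± 1241 against 17098 ± 2603), which can share reads. Of the genes for cytosolic ribosomal proteins 38 of 83 rose, of those for the respiratory chain 16 of 75 and of those for the proteasome 9 of 36, such as Rpl23a (189 ± 9.70 against 27.9 ± 9.91 FPKM), Ndufa12 of complex I (259 ± 31.8 against 28.0 ± 9.12) and the proteasome lid subunit Psmd7 (296 ± 17.7 against 42.1 ± 8.34). The paternally expressed imprinted gene Impact, a regulator of translation (mm9 chromosome 18, 13130761 to 13151457), had the largest rise, from 1.10 ± 1.08 to 134 ± 43.6 FPKM (log2 fold change 6.06 ± 0.54, adjusted p = 0.00239).

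Of 11795 genes tested, 750 were called, 573 higher and 177 lower, each with every KO embryo library on the same side of both controls. Of all genes tested 36.3% had this arrangement, which chance gives 20% of genes. With so few libraries a call all but requires it, here and in the other comparisons, so it adds no support. After Impact the largest rises were those of Cox17, a copper chaperone of cytochrome oxidase (5.53 ± 1.28; 0 and 74.3 FPKM in the controls against 343 to 469), the kelch protein gene Klhl10 (5.40 ± 0.57), the ribosomal protein gene Rpl26 (5.27 ± 0.85), and the imprinted retrogene Mcts2 (5.09 ± 0.56). They were followed by Ankmy2 (5.07 ± 0.56), Ndufb7 (4.80 ± 1.05), the complex III gene Uqcr11 (4.72 ± 0.75, listed at 0 in both controls and at 17.7, 9.75 and 90.4 in the KO embryos), Spast, which encodes a microtubule-severing enzyme (4.71 ± 0.97), and Dnph1 (4.66 ± 0.51, listed at 0 in both controls). Uqcr11 and other genes of general use were listed at 0 in some libraries, so such a value is not read as absence. The largest falls were those of Zscan4f (−5.03 ± 1.19), Wbp5 (−4.72 ± 0.63), D16Ertd519e (−4.44 ± 0.90), the membrane-bending factor gene Pacsin2 (−4.41 ± 0.64), Tmem213 (−4.37 ± 0.56) and Zscan4c (−4.36 ± 0.91). The transcription factor genes Zfp281 (−4.35 ± 0.56), Sp8 (−4.33 ± 0.65) and Sox11 (−4.32 ± 0.81) fell too, as did Cd7 (−4.24 ± 0.74). Adjusted p over these 20 genes ran from 0.00239 for Impact to 0.0372 for Zscan4f. Among predicted and microRNA genes Gm3139 rose most (4.96 ± 0.86) and Mir363 fell most (−6.57 ± 1.07).

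The two-cell list held 35 tested members, of which 1 rose, 10 fell and 24 did not pass the test (5 rose and 15 fell adjusted over the list alone). The list was called lower by camera (mean log2 fold change −1.28, adjusted p = 5.47e-07; adjusted p = 0.279 with an estimated correlation). Usp17lc, a deubiquitinase gene, was at 18.8, 11.1 and 20.9 FPKM in the KO embryos against 184 and 99.3. The member that rose, Dppa2, known as an upstream activator of two-cell genes, was at 248 ± 38.0 against 47.8 ± 0.513. Of the 6 Zscan4 members Zscan4f, Zscan4c, Zscan4e (−4.03 ± 0.81) and Zscan4a (−2.60 ± 0.65) fell, while Zscan4b (−2.45 ± 1.03, adjusted p = 0.187) and Zscan4d (−1.73 ± 0.77, adjusted p = 0.212) did not pass (0 rose and 6 fell adjusted over the list alone). Camera called this family lower (mean −3.37, adjusted p = 1.42e-06; adjusted p = 0.261 with an estimated correlation). The exact two-sided permutation test of its sum gave p = 0.2, the smallest that 10 splits allow. The members are near-identical in sequence, so single values are uncertain. They also belong to the two-cell list, so the results of these 2 lists are not independent in any comparison. Trim28, which encodes the KAP1 corepressor, stood at 24.2 ± 11.3 FPKM against 8.10 ± 1.65 (1.37 ± 0.53, adjusted p = 0.150).

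Of 40 maternal oocyte genes 8 fell and 0 rose (20 fell adjusted over the list alone; mean −1.32, adjusted p = 3.62e-13; adjusted p = 0.261 with an estimated correlation). Among them were Oas1d (19.6 ± 7.20 against 107 ± 26.3 FPKM) and Obox2 (67.5 ± 4.71 against 277 ± 119). Of 83 ribosomal protein genes 38 rose and 0 fell (56 adjusted over the list alone; mean 1.93, adjusted p = 8.27e-19). Of 75 oxidative phosphorylation genes 16 rose (25 adjusted over the list alone; mean 1.43, adjusted p = 1.39e-07), and of 36 proteasome genes 9 rose (16 adjusted over the list alone; mean 1.40, adjusted p = 5.47e-07). These 3 lists each had an adjusted p of 0.261 with an estimated correlation. Of 30 lysosome and autophagy genes 5 rose (8 adjusted over the list alone; mean 0.96, adjusted p = 0.00360; adjusted p = 0.261 with an estimated correlation). Map1lc3b, an autophagosome protein gene, was at 4940.4 ± 740.0 against 1069 ± 529 FPKM, and Lamp2 at 95.6 ± 2.84 against 26.8 ± 11.1. Of 35 DNA replication genes 6 rose (8 adjusted over the list alone; mean 0.87, adjusted p = 0.0394; adjusted p = 0.348 with an estimated correlation), including the helicase subunit gene Mcm6 at 38.7 ± 6.86 against 9.58 ± 2.30 FPKM. None of 37 mitosis genes passed singly (0 adjusted over the list alone), while the list was called higher (mean 0.73, adjusted p = 0.0197; adjusted p = 0.261 with an estimated correlation). With median-of-ratios scaling the replication and mitosis lists were no longer called (means 0.37 and 0.09, adjusted p = 0.197 and 0.455). Both calls were also lost without control embryo 2 (adjusted p = 0.273 and 0.262) and without KO embryo 3 (0.0569 for both). The replication call was lost under each other scaling and whenever a knockout library was left out (adjusted p = 0.0501 to 0.0692). The mitosis call was also lost with quantile normalization (mean 0.44, adjusted p = 0.0692), a minimum of 5 FPKM (0.112), the replicate number as a block (0.0598) and without the length trend (0.0532). Adjusted p of the lists that were not called was 0.682 for pluripotency, 0.219 for trophectoderm, 0.374 for primitive endoderm, 0.163 for germ layer, 0.550 for p53 and apoptosis and 0.426 for integrated stress genes. It was 0.119 for heat shock, 0.230 for telomere maintenance, 0.550 for homologous recombination, 0.119 for CUL4-DDB1 ligase and 0.119 for KAP1 and heterochromatin genes. For the rest it was 0.261 for imprinted, 0.221 for replication-dependent histone, 0.383 for glycolysis and 0.109 for cholesterol synthesis genes. Of these, fry called higher the telomere maintenance (adjusted p = 0.0470), CUL4-DDB1 ligase (0.0185), KAP1 and heterochromatin (0.0339) and imprinted lists (0.0318).

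Among markers of other cells, the cumulus and granulosa list was not called (adjusted p = 0.0743), and 1 of its 4 tested members, Tnfaip6, fell (17.08 and 12.02 FPKM in the controls, and 0, 2.33 and 0 in the KO embryos). Fibroblast markers (adjusted p = 0.219) and blood markers (adjusted p = 0.781) were not called. The Y-linked Eif2s3y was listed at 0 in both controls and at 2.78, 8.86 and 2.92 FPKM in the KO embryos, which also held Xist, the X-inactivation RNA, at 5.49 ± 1.81 FPKM against 1.34 ± 0.978. Xist did not pass the test (adjusted p = 0.156).

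The median log2 fold change of all genes tested was 0.31, and median-of-ratios scaling moved it by −0.35, quantile normalization by −0.27 and removal of the trend with gene length, chosen after seeing the data, by −0.32. The higher share of the called genes was 76.4% as deposited, 35.9%, 56.9% and 54.5% with those settings. The median log2 fold change was 0.02 without control embryo 1 and 0.74 without control embryo 2. Without control embryo 1, 540 genes were called. The count was 1817 without control embryo 2, 88 without KO embryo 1, 270 without KO embryo 2, 87 without KO embryo 3, 385 without KO arrest 2 and 463 without KO arrest 3. Other settings gave 269 with no filter on low values, 82 with weights per library, 1709 with all 12 libraries in 1 fit and 228 with only the 2 groups compared.

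The comparison of KO arrest with control embryos asks how the knockout libraries marked as arrested differ from wild type. Ribosomal protein genes were higher in them, with 72 of 83 rising, as were the respiratory chain with 48 of 75 and the proteasome with 30 of 36. Examples were Rpl41 (23853 ± 4138 FPKM, SD, n = 3, against 1417 ± 630, SD, n = 2), the complex III subunit gene Uqcrh (580 ± 36.8 against 34.8 ± 4.84) and the proteasome core subunit gene Psma6 (514 ± 111 against 16.4 ± 4.05). Of 40 oocyte genes 23 fell and 1 rose, with Omt2b at 530 ± 110 against 23905 ± 4477 FPKM and Oog3 at 76.7 ± 10.3 against 3769 ± 2913. The Zscan4 sum was 12.9 ± 6.57 FPKM against 682 ± 436, 53.01-fold lower, or 29.1-fold without control embryo 2 (exact two-sided permutation p = 0.2, the smallest possible), while Dppa2 rose to 695 ± 84.5 against 47.8 ± 0.513.

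Of 11795 genes, 2976 were called, 1930 higher and 1046 lower, each separating the 3 KO arrest from the 2 control libraries (48.8% of all genes tested, 20% by chance). The largest rises were those of the ribosomal protein gene Rps4x (mm9 chromosome X, 99380282 to 99383710; 372 ± 146 FPKM against 0.320 ± 0.00601, log2 fold change 8.05 ± 1.25 in the fit), Uqcr11 (7.92 ± 0.75), and the complex I gene Ndufs5 (7.61 ± 0.47; 196, 223 and 275 FPKM against 0 and 0.381). Next came Rpl26 (7.05 ± 0.85), Ndufa1 (7.02 ± 1.54), Rpl34 (6.91 ± 0.88), Ndufs6 (6.77 ± 0.56), Mnf1 (6.76 ± 1.23), Chchd1 (6.76 ± 0.58) and Rpl5 (6.69 ± 0.72). Of the genes with systematic names BC002163 rose most (174, 207 and 249 FPKM against 0.142 and 1.32), which is uncertain because copies of housekeeping genes can share reads. Uqcr11, Ndufs6 and Mnf1 were listed at 0 in both controls. The largest falls were those of D16Ertd519e (−7.48 ± 0.90), Zscan4f (−6.63 ± 1.19), Tcl1b4 (−6.61 ± 0.80) and Tcl1b3 (−5.80 ± 0.61) of the Tcl1 oncogene family, Prl8a2 (−6.06 ± 0.61), and S100a9, a calcium-binding protein gene of neutrophils (−6.03 ± 0.54). Others were the oocyte gene C86187 (−5.91 ± 0.64), Gbas (−5.89 ± 0.95), the chemokine gene Cxcl13 (−5.81 ± 0.89) and the selenophosphate synthetase gene Sephs2 (−5.77 ± 0.72). Among the predicted and systematically named genes, ranked apart, AA545190 fell most (−6.31 ± 0.67). Prl8a2, S100a9 and Cxcl13 were listed at 0 in all 3 KO arrest libraries. Adjusted p over these 22 genes ran from 4.54e-05 for Ndufs5 to 0.00861 for Ndufa1.

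In the two-cell list 8 members rose and 8 fell of 35 (10 and 8 adjusted over the list alone). The two-cell list had a median log2 fold change of 0.36 and a mean of −0.40, opposite in sign, and camera did not call it (Down, adjusted p = 0.381; adjusted p = 0.862 with an estimated correlation). The 6 Zscan4 genes belong to this list and are among the 8 that fell, while all 8 that rose lie outside that family. The negative mean thus rests on the Zscan4 members. All 6 Zscan4 genes fell (6 adjusted over the list alone; mean −5.02, adjusted p = 2.84e-06; adjusted p = 0.186 with an estimated correlation), from −3.39 ± 1.03 for Zscan4b to −6.63 ± 1.19 for Zscan4f. Of 40 maternal oocyte genes 23 fell and 1 rose (27 and 1 adjusted over the list alone; mean −2.50, adjusted p = 5.26e-16). Counts adjusted over the list alone were 76 higher and 1 lower for ribosomal protein (mean 3.51, adjusted p = 1.08e-25; 72 rose and 1 fell over all genes). They were 55 higher for oxidative phosphorylation (mean 2.97, adjusted p = 5.97e-15) and 32 higher for proteasome genes (mean 2.87, adjusted p = 5.01e-13). The oocyte list and these 3 lists had an adjusted p of 0.186 with an estimated correlation. Of 30 lysosome and autophagy genes 12 rose and 1 fell (14 and 1 adjusted over the list alone; mean 1.69, adjusted p = 0.000379; adjusted p = 0.202 with an estimated correlation). Gabarapl2, an autophagosome protein gene, was at 1675 ± 277 against 95.6 ± 34.4 FPKM.

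Of 29 p53 and apoptosis genes 11 rose and 0 fell (11 adjusted over the list alone; mean 1.86, adjusted p = 0.000379; adjusted p = 0.495 with an estimated correlation). They included the cyclin gene Ccng1 at 91.0, 40.1 and 91.1 FPKM against 0.141 and 6.32, the cell death effector gene Bax at 89.2 ± 25.1 against 5.57 ± 7.55, and Phlda3, listed at 0 in both controls and at 16.0, 3.96 and 24.0 in KO arrest. Of 14 heat shock genes 6 rose (7 adjusted over the list alone; mean 1.48, adjusted p = 0.0463; adjusted p = 0.495 with an estimated correlation), with the chaperone gene Hspa8 at 1334 ± 606 against 41.5 ± 21.3 FPKM. Of 35 DNA replication genes 9 rose (12 adjusted over the list alone; mean 1.17, adjusted p = 0.0410; adjusted p = 0.495 with an estimated correlation), with Gins1 at 62.3, 98.7 and 71.3 FPKM against 0.798 and 4.49. The heat shock and replication lists were not called with median-of-ratios scaling (means 0.89 and 0.62, adjusted p = 0.0763 and 0.152) or with quantile normalization (means 0.87 and 0.73, adjusted p = 0.0858 for both). The heat shock list was also lost without control embryo 1 (mean 0.95, adjusted p = 0.0660) and the replication list without control embryo 2 (mean 1.39, adjusted p = 0.177). The heat shock call was lost without each KO embryo library as well (adjusted p = 0.0579 to 0.0688), and the replication call with TPM scaling (0.121) and without KO arrest 2 (0.116) or KO embryo 1 (0.0571). Trim28 was at 21.5 ± 2.15 FPKM against 8.10 ± 1.65 (1.32 ± 0.53, adjusted p = 0.0922). Adjusted p of the lists that were not called was 0.277 for pluripotency, 0.899 for trophectoderm, 0.123 for primitive endoderm, 0.379 for germ layer and 0.792 for integrated stress genes. It was 0.299 for telomere maintenance, 0.776 for homologous recombination, 0.299 for CUL4-DDB1 ligase and 0.776 for KAP1 and heterochromatin genes. For the rest it was 0.774 for imprinted, 0.423 for mitosis, 0.299 for replication-dependent histone, 0.861 for glycolysis, 0.951 for cholesterol synthesis and 0.268 for cumulus and granulosa genes. Of these, fry called higher the pluripotency (adjusted p = 0.0127), telomere maintenance (0.0127), CUL4-DDB1 ligase (0.0117) and mitosis lists (0.0122).

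Transcripts of blood and connective tissue moved with these groups. Of 12 fibroblast markers 4 fell (5 adjusted over the list alone; mean −1.51, adjusted p = 0.000379; adjusted p = 0.509 with an estimated correlation). Of 8 blood and immune markers 3 fell (4 adjusted over the list alone; mean −1.77, adjusted p = 0.0113; adjusted p = 0.495 with an estimated correlation). The collagen gene Col1a2 was at 6.85 and 20.8 FPKM in the controls, the lysozyme gene Lyz2 at 6.75 and 21.5 and the globin gene Hbb-bs at 5.14 and 21.7, and all 3 were listed at 0 in every KO arrest library. Xist was at 0.649 and 2.03 FPKM in the controls and at 0, 0.143 and 0.231 in KO arrest, and Eif2s3y was listed at 0 in all 5 libraries.

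The median log2 fold change of all genes was 0.45, and it moved by −0.23 with TPM scaling, −0.41 with median-of-ratios scaling, −0.38 with quantile normalization and −0.38 without the length trend. The higher share of the called genes was 64.9% as deposited, and 50.6%, 45.1%, 48.9% and 50.2% with those settings, so the split between higher and lower calls rests on the scaling. The median log2 fold change was 0.16 without control embryo 1 and 0.88 without control embryo 2. Without control embryo 1, 2153 genes were called, and 1983 without KO arrest 2, while weights per library gave 1505.

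**Figure D2:**
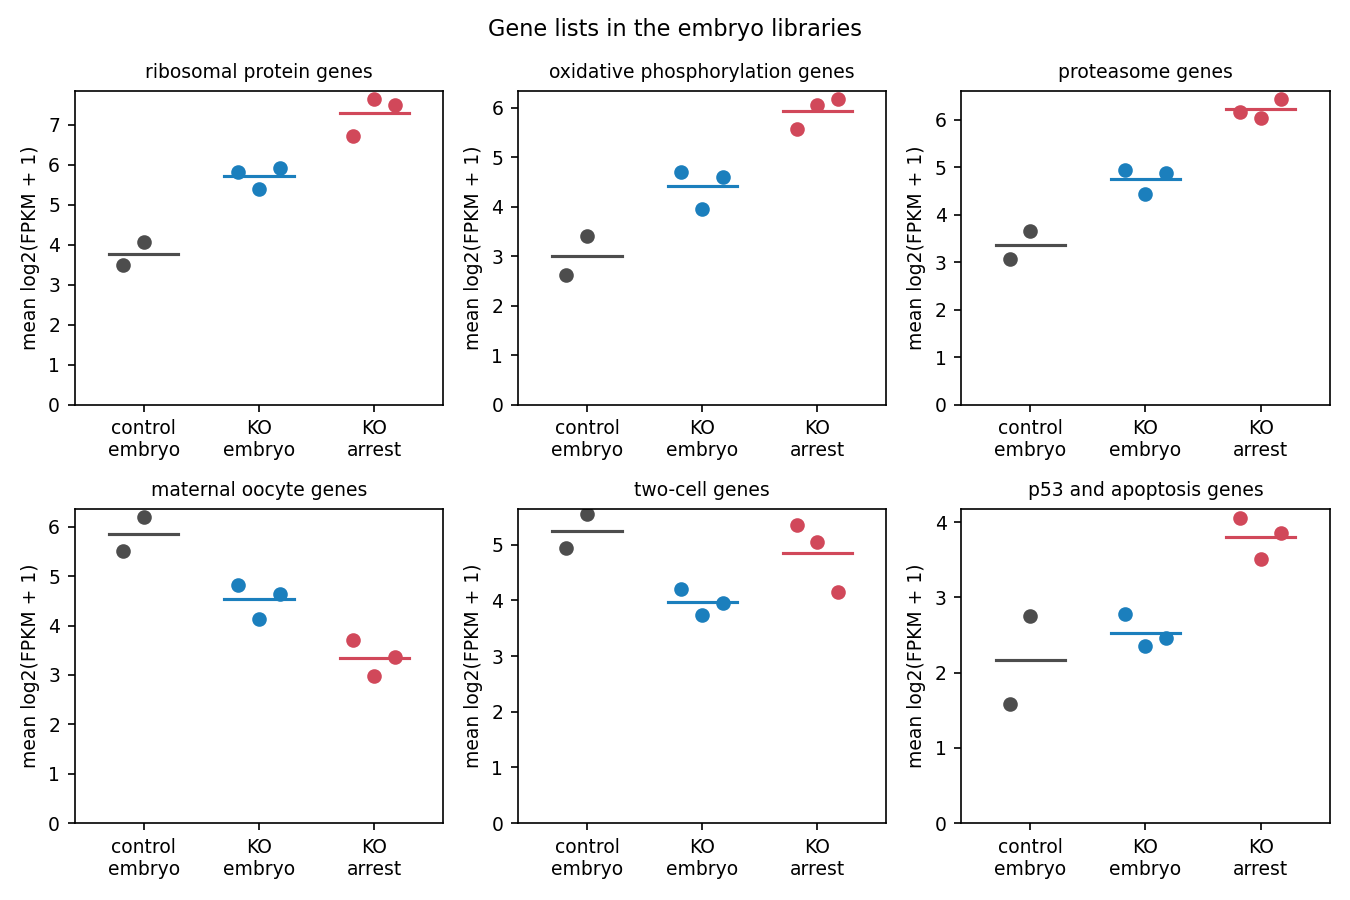
Mean log2(FPKM + 1) of 6 gene lists in each embryo library; points are libraries, bars are group means and each axis starts at 0. The ribosomal protein list stood at 3.48 and 4.07 in the control embryos, 5.40 to 5.91 in the KO embryos and 6.72 to 7.64 in the KO arrest libraries. In the same order the maternal oocyte list stood at 5.50 and 6.20, 4.14 to 4.81 and 2.97 to 3.71.

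The comparison of KO arrest with KO embryos sets the 2 kinds of knockout library against each other. Blood and connective tissue transcripts showed the largest falls: S100a9 (mm9 chromosome 3, 90496555 to 90499613) was at 157, 159 and 245 FPKM in the KO embryos and listed at 0 in all KO arrest libraries. Also listed at 0 there were S100a8, Lyz2, Col1a2, the neutrophil granule protein gene Ngp and Hbb-bs. Of the ribosomal protein genes 31 of 83 rose and of the proteasome genes 10 of 36, for example Rpl7 (420.0 ± 111.6 FPKM, SD, n = 3, against 67.0 ± 11.7, SD, n = 3) and the proteasome gene Psmb6 (288 ± 63.3 against 25.8 ± 10.3). Of 29 p53 and apoptosis genes 7 rose, among them the cell cycle inhibitor gene Cdkn1a at 216 ± 94.1 against 11.9 ± 10.8 FPKM. The oocyte gene Omt2b was at 530 ± 110 against 9163 ± 1806 FPKM.

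Of 11795 genes, 1012 were called, 581 higher and 431 lower, each separating the groups (37.1% of all genes tested, 10% by chance). The largest rises were those of the complex I gene Ndufs6 (6.77 ± 0.50; 105, 85.9 and 139 FPKM in KO arrest and listed at 0 in every KO embryo library), the splicing factor gene Snrpf (5.87 ± 0.54, likewise listed at 0), Cox19 (5.84 ± 0.99) and the inhibitor of differentiation gene Id3 (5.77 ± 0.73). They were followed by Ndufa3 (5.49 ± 0.84), Rps4x (5.47 ± 1.12), the thioredoxin gene Txn1 (5.46 ± 0.86), Dynap (5.20 ± 0.83), Nme4 (5.12 ± 0.99) and the proton pump gene Atp6v1f (5.12 ± 0.68), and BB287469 (5.03 ± 1.18). The largest falls were S100a9 (−7.52 ± 0.48), S100a8 (−5.58 ± 0.91), Lyz2 (−4.88 ± 0.56), Col1a2 (−4.74 ± 0.56) and the ubiquitin ligase gene Siah2 (−4.69 ± 0.34; 9.67 ± 2.78 against 270 ± 39.2 FPKM). Below these lay Ngp (−4.42 ± 0.56), Hbb-bs (−4.27 ± 0.63), the clock gene Per3 (−4.24 ± 0.59; 2.33 ± 2.54 against 53.1 ± 18.5), Eps8 (−4.21 ± 0.54) and the cyclin gene Ccng2 (−4.19 ± 0.59; 0.234 ± 0.234 against 23.2 ± 10.6). Among the predicted and systematically named genes, ranked apart, 0610040F04Rik fell most (−4.83 ± 0.58). Adjusted p over these 22 genes ran from 0.000130 for S100a9 to 0.0275 for BB287469.

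Of 35 two-cell genes 8 rose and 1 fell (15 and 2 adjusted over the list alone; mean 0.88, adjusted p = 0.00257; adjusted p = 0.487 with an estimated correlation). Those with the smallest p were Gm5662 (1495 ± 993 against 60.6 ± 18.4 FPKM), Gm2016 (783 ± 497 against 33.9 ± 10.5) and Gm8300 (332 ± 217 against 28.8 ± 9.46), near-identical genes that can share reads, and the arginase gene Arg2 (78.5 ± 17.7 against 16.5 ± 7.15). The Zscan4 sum lay on the other side, at 12.9 ± 6.57 against 64.5 ± 20.6 FPKM (exact two-sided permutation p = 0.1, the smallest that this design allows). Of its 6 members Zscan4a fell (−2.64 ± 0.58; 2 adjusted over the list alone; family mean −1.65, adjusted p = 0.0114; adjusted p = 0.396 with an estimated correlation). Of 40 maternal oocyte genes 10 fell (14 fell and 1 rose adjusted over the list alone; mean −1.18, adjusted p = 8.63e-08). Of 83 ribosomal protein genes 31 rose (46 adjusted over the list alone; mean 1.58, adjusted p = 1.10e-17), and of 75 oxidative phosphorylation genes 21 (31 adjusted over the list alone; mean 1.54, adjusted p = 2.48e-11). Of 36 proteasome genes 10 rose (21 adjusted over the list alone; mean 1.47, adjusted p = 2.35e-10), of 30 lysosome and autophagy genes 4 (8 adjusted over the list alone; mean 0.74, adjusted p = 0.0114). Of 29 p53 and apoptosis genes 7 rose (12 adjusted over the list alone; mean 1.43, adjusted p = 3.28e-05). The oocyte list and these 5 lists had an adjusted p of 0.396 with an estimated correlation.

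Of 54 replication-dependent histone genes 4 rose (3 adjusted over the list alone; mean 0.95, adjusted p = 0.00198; adjusted p = 0.538 with an estimated correlation), among them Hist1h4d at 446 ± 141 against 16.1 ± 14.3 FPKM. The histone list was not called once the length trend was removed (mean 0.27, adjusted p = 0.514). Of 25 pluripotency genes 2 rose (2 adjusted over the list alone; mean 0.75, adjusted p = 0.0484; adjusted p = 0.456 with an estimated correlation). They were Tdgf1 at 72.4 ± 42.4 against 1.78 ± 2.04 FPKM and Nanog at 6.40, 4.61 and 10.9 against 0, 0.633 and 0. The pluripotency call was lost under quantile normalization (adjusted p = 0.106) and TPM scaling (0.0595). It was also lost without control embryo 1 or 2, KO arrest 2 or 3, or KO embryo 2 or 3 (adjusted p = 0.0521 to 0.143). The imprinted call was lost with TPM scaling (adjusted p = 0.0636) and without KO arrest 2 (0.0771) or KO embryo 1 (0.0562), and the lysosome call with TPM scaling (0.0595). Of 22 imprinted genes 5 fell (7 fell and 1 rose adjusted over the list alone; mean −0.73, adjusted p = 0.0371; adjusted p = 0.396 with an estimated correlation). Among them were Impact at 15.4 ± 3.94 against 134 ± 43.6, Mcts2 at 9.78 ± 4.82 against 93.5 ± 15.5 and Mest at 0.773, 0.125 and 0 against 18.4, 11.8 and 11.6. Of 12 fibroblast markers 7 fell (10 adjusted over the list alone; mean −2.18, adjusted p = 1.15e-07), and of 8 blood markers 3 fell (5 adjusted over the list alone; mean −1.97, adjusted p = 0.00240). Both lists had an adjusted p of 0.396 with an estimated correlation. Among the imprinted members the connective tissue gene Dcn was listed at 0 in KO arrest and at 4.79, 3.94 and 7.09 in the KO embryos. The sex-linked Xist (−2.50 ± 0.52, adjusted p = 0.0190) and Eif2s3y (−2.40 ± 0.51, adjusted p = 0.0195) fell. Adjusted p of the lists that were not called was 0.306 for trophectoderm, 0.254 for primitive endoderm, 0.949 for germ layer, 0.935 for integrated stress and 0.0711 for heat shock genes. It was 0.936 for telomere maintenance, 0.949 for homologous recombination, 0.949 for CUL4-DDB1 ligase, 0.344 for KAP1 and heterochromatin and 0.596 for DNA replication genes. For the rest it was 0.306 for mitosis, 0.269 for glycolysis, 0.0998 for cholesterol synthesis and 0.946 for cumulus and granulosa genes. Of these, fry called only the glycolysis list, higher (adjusted p = 0.0420). Trim28 was at 21.5 ± 2.15 against 24.2 ± 11.3 FPKM (adjusted p = 0.956), and Dcaf11 did not pass (0.42 ± 0.85, adjusted p = 0.800).

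The median log2 fold change was 0.07 and moved by −0.34 with TPM scaling. The higher share of the called genes was 57.4% as deposited, 29.3% with TPM scaling, 47.1% with quantile normalization and 47.0% without the length trend. The count was 1995 without control embryo 1, 2023 without control embryo 2, 373 and 335 without KO arrest 2 and 3, and 368, 285 and 393 without KO embryo 1, 2 and 3. It was 456 with no filter, 2555 with weights per library, 2081 with all 12 libraries and 2030 with only the 2 groups compared.

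**Figure D3:**
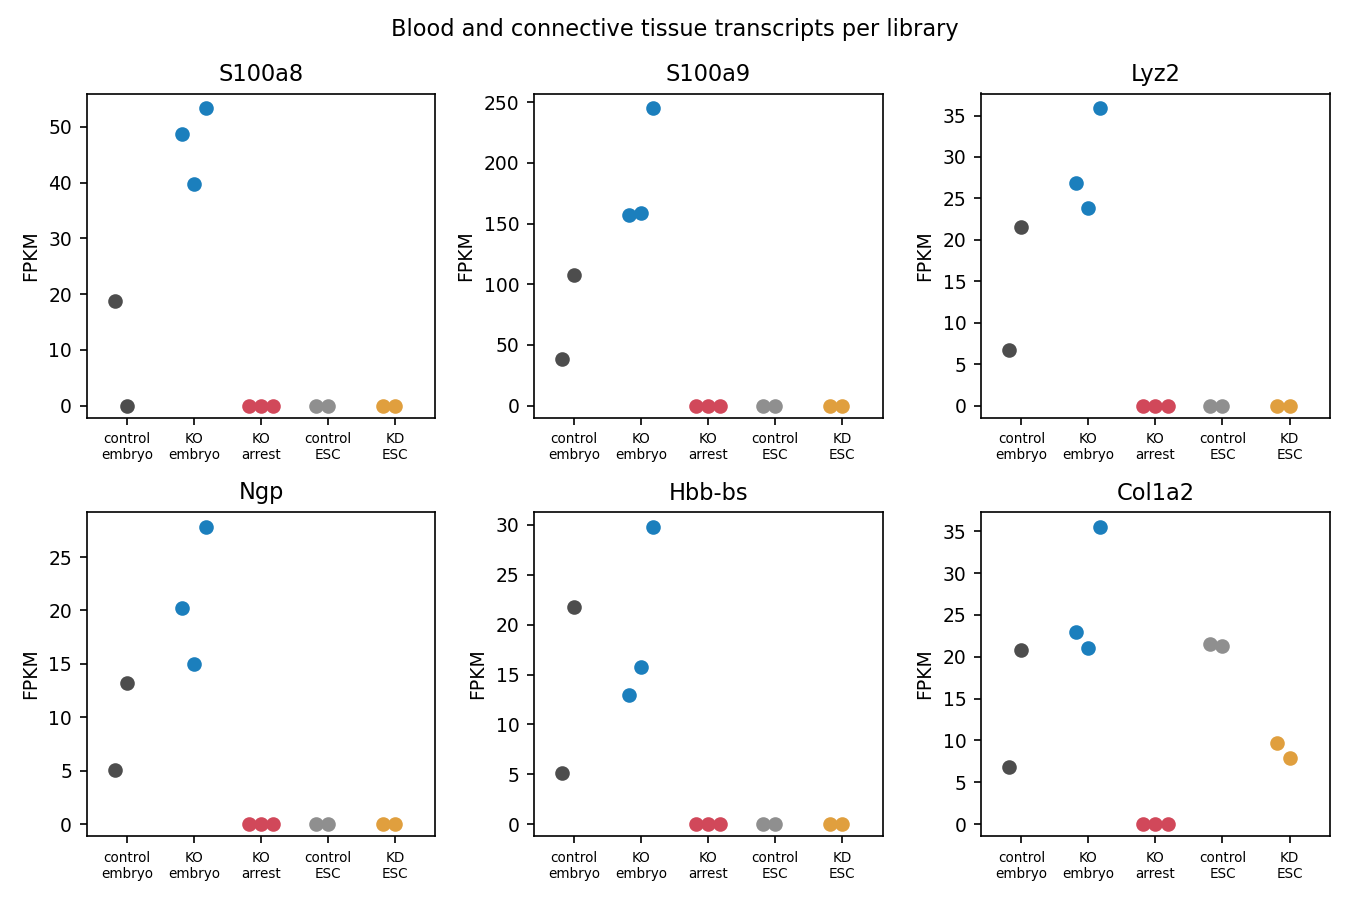
FPKM of 6 transcripts of blood and connective tissue in each library, linear axes; points are libraries. All 6 were listed at 0 in the 3 KO arrest libraries and all but Col1a2 in the 4 ES cell libraries, while S100a9 ranged from 38.1 to 245 in the control and KO embryos and S100a8 was also listed at 0 in control embryo 2.

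KO embryos and KO arrest libraries were set against the same 2 control libraries. Across 11795 genes, which are not independent, the fold changes correlated at r = 0.706 (jackknife SE over libraries 0.0987). Simulated unchanged groups that shared simulated controls gave 0.599. The covariance was 1.55 against a simulated 0.317, a difference of 1.23. The simulation gave all groups the same spread, but the control embryos correlated less with each other (r = 0.774) than libraries of either knockout group (0.888 to 0.919). It can therefore understate what shared controls alone give, and these differences do not settle whether the 2 knockout groups share an effect. Higher calls shared by both numbered 493 and lower calls 138, among them Zscan4f and Zscan4c. No chance value was computed for these counts under shared controls, and splitting the controls would leave 1 library in each part.

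The knockdown in ES cells asks whether lowering Dcaf11 changes transcripts in culture. The Zscan4 sum was 5.06 ± 0.307 FPKM (SD, n = 2) in the KD ESC libraries against 49.1 ± 7.24 (SD, n = 2) in the controls, 9.70-fold lower (exact two-sided permutation p = 0.333, the smallest that 2 against 2 allows). Of 22 two-cell genes tested 9 fell and 0 rose (16 fell and 1 rose adjusted over the list alone), among them Zscan4c (1.22 ± 0.218 against 11.6 ± 0.259 FPKM), Zscan4b (0.782 ± 0.0428 against 6.61 ± 0.360) and Gm2016 (3.21 ± 0.487 against 14.3 ± 1.33). The two-cell list was called lower (mean −1.30, adjusted p = 4.23e-06; adjusted p = 0.584 with an estimated correlation). The reticulon gene Rtn4 (mm9 chromosome 11, 29592898 to 29644414) was at 171 and 135 FPKM in KD ESC against 2.83 and 1.99, and Tmsb10, which encodes an actin-binding thymosin (mm9 chromosome 6, 72907341 to 72908742), fell most, from 641 ± 4.11 to 25.7 ± 0.259.

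Of 12264 genes, 764 were called, 318 higher and 446 lower, each separating the groups (62.5% of all genes tested, 33.3% by chance), and 309 of them changed at least 2-fold. Large rises were those of Rtn4 (5.50 ± 0.19), the transcription elongation factor gene Tcea1 (4.28 ± 0.13), the glyoxalase gene Glo1 (4.02 ± 0.12) and Gpatch4 (3.94 ± 0.17). Next were the actin nucleator gene Arpc4 (3.60 ± 0.12), Golga7 (3.54 ± 0.52), Jagn1 (3.49 ± 0.12), the small GTPase gene Rab6a (3.18 ± 0.17) and the kinase gene Dyrk1a (2.97 ± 0.23). Among the predicted and systematically named genes, ranked apart, 1810058I24Rik rose most (4.22 ± 0.29). Falls after Tmsb10 (−4.59 ± 0.07) were those of Zfp518b (−4.41 ± 0.13), the splicing factor gene Srsf1 (−4.37 ± 0.74), S100a6 (−4.21 ± 0.21, listed at 0 in both KD ESC libraries) and Uqcr11 (−3.85 ± 0.48; 0 and 1.55 FPKM against 20.6 and 23.6). Next were Vmn1r47 (−3.20 ± 0.27), the ATP synthase genes Atp5l (−3.13 ± 0.16) and Atp5g1 (−2.96 ± 0.13), Zscan4a (−2.88 ± 0.32), the cytochrome oxidase gene Cox5a (−2.77 ± 0.25) and 2610306M01Rik (−3.67 ± 0.20). Adjusted p over these genes ran from 0.000797 for Tmsb10 to 0.0497 for Srsf1.

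Jumps of more than 4-fold also occurred within a group: 145 genes differed that much between the control ESC libraries, 192 between the KD ESC libraries and 41 in both pairs. If such jumps fell at random on the 4 libraries, 20.5 genes would separate the groups, and 58 did, 22 higher and 36 lower in KD ESC.

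Of the 6 Zscan4 genes 5 fell (6 adjusted over the list alone; mean −2.29, adjusted p = 6.54e-05; adjusted p = 0.584 with an estimated correlation), and Zscan4f did not pass (−2.37 ± 0.55, adjusted p = 0.0765). Of 67 replication-dependent histone genes 15 fell and 2 rose (39 and 2 adjusted over the list alone; mean −0.36, adjusted p = 4.23e-06), with Hist1h4h at 562 ± 38.5 against 1075 ± 41.0 FPKM. Of 36 DNA replication genes 7 fell (12 fell and 1 rose adjusted over the list alone; mean −0.29, adjusted p = 0.0176), with Mcm2 at 57.9 ± 0.934 against 105 ± 2.01. Of 74 oxidative phosphorylation genes 13 fell and 1 rose (20 and 1 adjusted over the list alone; mean −0.53, adjusted p = 0.00411), with Atp5g1 at 5.45 ± 0.560 against 49.2 ± 3.82 FPKM. Of 20 fibroblast markers 6 fell (9 adjusted over the list alone; mean −0.76, adjusted p = 9.95e-05), with the matrix protein gene Thbs1 at 36.0 ± 0.316 against 70.8 ± 0.713. These 4 lists had an adjusted p of 0.584 with an estimated correlation. Without KD ESC 1 the replication (mean −0.26, adjusted p = 0.0555) and oxidative phosphorylation lists (mean −0.44, adjusted p = 0.0748) were not called. Among genes of the germ line Dazl rose to 65.8 ± 2.07 from 15.7 ± 2.21 FPKM and Khdc3 fell to 17.7 ± 1.67 from 44.3 ± 3.60. The maternal oocyte list was not called (adjusted p = 0.160). Trim28 was at 180.2 ± 12.5 against 199.6 ± 13.3 FPKM (−0.15 ± 0.09, adjusted p = 0.338).

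Adjusted p of the other lists in ES cells was 0.240 for pluripotency, 0.946 for trophectoderm, 0.0621 for primitive endoderm, 0.204 for germ layer, 0.669 for p53 and apoptosis, 0.895 for integrated stress and 0.827 for heat shock genes. It was 0.6 for telomere maintenance, 0.397 for homologous recombination, 0.895 for CUL4-DDB1 ligase, 0.612 for KAP1 and heterochromatin, 0.669 for imprinted and 0.397 for mitosis genes. For the rest it was 0.215 for ribosomal protein, 0.6 for proteasome, 0.971 for glycolysis, 0.0787 for cholesterol synthesis, 0.612 for lysosome and autophagy, 0.204 for cumulus and granulosa and 0.301 for sex-linked genes. By fry the heat shock (adjusted p = 0.0326), ribosomal protein (0.0392) and cumulus and granulosa lists (0.0187) were called lower. The maternal oocyte list was called higher by fry (0.0267). Of the blood markers 3 were measured, too few for the test, and Laptm5 fell (26.7 and 23.6 against 46.4 and 54.3 FPKM). All 4 ES cell libraries held both Xist, at 14.9 and 16.7 FPKM in KD ESC and 20.0 and 18.4 in control ESC, and Eif2s3y, at 15.2 and 18.9 and at 14.5 and 22.8.

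The higher share of the called genes was 41.6% as deposited, 55.1% with median-of-ratios scaling and 55.9% without the length trend, and the median log2 fold change of −0.09 moved by less than 0.1 under each scaling. With single libraries left out the share was 92.3% of 13 genes without control ESC 1, 90.0% of 30 without control ESC 2 and 28.5% of 375 without KD ESC 1. The count was 313 with no filter and 93 with all 12 libraries in 1 fit.

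**Figure D4:**
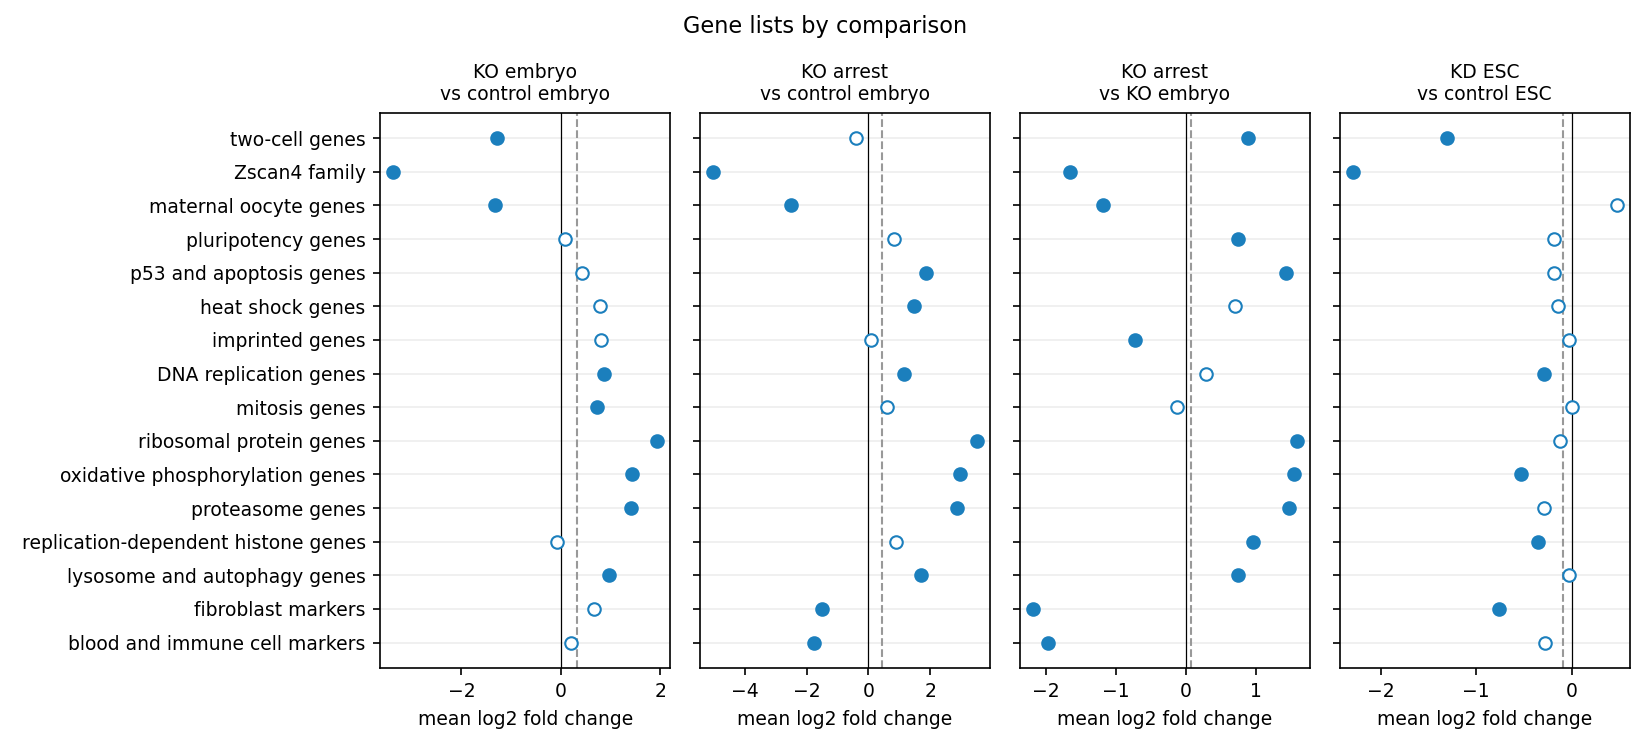
Mean log2 fold change of the 16 gene lists called in at least 1 comparison, by comparison; filled points were called by camera, open points were not called or, for blood markers in ES cells, not tested, and the dashed line is the median of all genes tested. The Zscan4 family lies at −3.37, −5.02, −1.65 and −2.29 from left to right, and the ribosomal protein list at 1.93, 3.51, 1.58 and −0.12.

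The effects in embryos and in ES cells were compared across the 9730 genes tested in both. The fold changes of KO embryos and KD ESC correlated at r = 0.02 and those of KO arrest and KD ESC at r = −0.03, with no library in common. Higher calls shared by KO embryos and KD ESC numbered 34 against 15.8 for independent lists and lower calls 10 against 3.42. Opposite calls numbered 31, higher in KO embryos and lower in KD ESC, against 20.1, and 3 the other way against 2.69. For KO arrest and KD ESC the shared calls numbered 78 against 51.7 and 21 against 24.8, and the opposite calls 85 against 65.8 and 26 against 19.5. The difference between the KO embryo and the KD ESC effect was itself tested over 14447 genes, of which 388 were called, 298 with the higher log2 fold change in embryos and 90 with the higher one in ES cells. None of the 6 Zscan4 genes was among them. The difference ran from 0.27 ± 0.87 for Zscan4a (adjusted p = 0.911) to −2.66 ± 1.78 for Zscan4f (adjusted p = 0.485). The higher share was 76.8% as deposited, 38.9% with median-of-ratios scaling, 61.9% with quantile normalization and 53.8% without the length trend. The count was 706 and 2020 without control embryo 1 and 2, and 51 and 39 without control ESC 1 and 2. It was 124 and 222 without KD ESC 1 and 2, 229 and 238 without KO embryo 1 and 3, and 257 with a pseudocount of 0.1.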

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

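The single genes named in this part from the difference between embryos and ES cells were chosen only after the result was seen, except Uqcr11, Atp5l and Atp5g1, which the rule for named genes already held. The difference between the KO embryo and the KD ESC effect, tested in 1 limma fit of 12 libraries, was called for 388 genes. Of these, 30 were also called in opposite directions in the 2 comparisons. The largest of them were Uqcr11, with a difference of 8.57 on the log2 scale (4.72 in embryos and −3.85 in ES cells), Atp5l with 6.15 (3.02 and −3.13), Nfkbia, which encodes an inhibitor of NF-kappa-B, with −5.03 (−3.68 and 1.35), Ceacam20 with −4.84 (−3.22 and 1.62) and Atp5g1 with 4.50 (1.54 and −2.96). Uqcr11 lay at or near the floor in control embryos and KD ESC, values not read as absence above, so its difference is uncertain. The share of the called differences that were higher in embryos was 76.8% as deposited and 38.9% with median-of-ratios scaling.

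The share of FPKM in rows without a gene name, which entered no test, was 1.18% in the lower of the KD ESC libraries and 1.19% in the higher, above the 1.14% and 1.07% of the control ESC libraries. Chance separates 2 libraries from 2 in 33.3% of cases, and 62.5% of genes tested in ES cells separated the groups, so this small gap carries little weight. No biological explanation was tested for these results.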

How the results depend on the processing

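Removal of the length trend was chosen only after the results were seen; the other settings were chosen before. Over 16 main results and 311 alternative values, 262 kept their side of the threshold or stayed within 1.5 times the count (3 of them, not called, with the opposite sign). Correlations counted as kept when they moved by less than their jackknife SE, which comes from the same left-out libraries and is rarely exceeded. Besides these, 44 counts moved further, 5 list calls were lost, and no Dcaf11 or two-cell list result reversed. A kept count can hold other genes: with median-of-ratios scaling KO embryo against control embryo called 251 higher and 449 lower, 428 of them shared with the 750. Of 2063 values for 104 list results 1923 kept their side of the threshold, 93 of them uncalled and opposite in sign, 100 lost and 39 gained a call and 1 reversed: the heat shock list in KD ESC, not called by camera, was called lower by fry (mean −0.14, adjusted p = 0.0326). Of 5037 values for 281 results of named genes 4405 kept their side, 24 of them uncalled and opposite in sign, 592 lost and 40 gained a call. The call of the two-cell list (means −1.28, 0.88 and −1.30) was lost with an estimated correlation in KO embryo (adjusted p = 0.279), KO arrest against KO embryo (0.487) and KD ESC (0.584), and by fry in the first 2 (0.0932 and 0.0998). The Zscan4 family was called lower by fry in KO embryo (adjusted p = 0.0176), KO arrest against control embryo (0.00302) and KD ESC (0.00862). In KO arrest against KO embryo fry called neither that family (0.0699) nor the histone list (0.158). In KD ESC it called neither the histone (0.187) nor the oxidative phosphorylation list (0.0731). The embryo fit gave its groups 1 spread, although control embryos correlated less with each other (0.774) than libraries of either knockout group (0.888 to 0.919). With weights per library 82 genes in place of 750 and 1505 in place of 2976 were called against controls. Between the knockout groups 2555 were called in place of 1012. Adjusted p may therefore be too small against controls and too large between the knockout groups. Beyond this, the cause of the moved counts was not tested.

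Counts of called genes moved by over 1.5 times as follows. For KO embryo against control embryo (750) they were 269 with no filter, 82 with weights, 1709 with 12 libraries, 228 with 2 groups and 87 to 1817 with 1 library left out. For KO arrest against control embryo (2976) they were 1505 with weights and 1983 without KO arrest 2, while the highest with 1 left out, 3636, stayed within 1.5 times. For KO arrest against KO embryo (1012) they were 456, 2555, 2081 and 2030 in the same order and 285 to 2023 with 1 left out. For KD ESC (764) they were 313 with no filter, 309 at a log2 change of at least 1, 93 with 12 libraries and 13, 30 and 375 without control ESC 1, control ESC 2 and KD ESC 1, while 686 without KD ESC 2 stayed within 1.5 times. For the difference (388) they were 257 with a pseudocount of 0.1, 234 without the length trend and 39 to 2020 with 1 left out. Of the named genes called, 21 of 51, 61 of 65, 44 of 66 and 12 of 46 kept their call with each library left out, in the order of the report, and none changed sign.

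With the replicate number as a block the counts were 76, 1965, 550, 26 and 127. Deviations from the group mean of libraries with the same number correlated at −0.11 to 0.02. In a group of 2 libraries such deviations mirror each other, so these values cannot show whether libraries with the same number share a litter, day or batch. Depth is known only in relative terms, and the lowest ratio, 0.373 in KO arrest 1, limits low genes most.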

Other observations

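The tests of shared reads between paralogs, of another stage and of the loss of Dcaf11, the removal of the length trend as a setting and the tissue lists were chosen only after the results were seen. Several members of the bone marrow list (S100a8, S100a9, Ngp, Lyz2 and Hbb-bs) and of the connective tissue list (Col1a2) had been seen before the lists were written.

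The gene with the highest FPKM differed between libraries, also within the control embryos and within the KO embryos. Dppa3, a maternal factor that protects DNA methylation, led in all 3 KO arrest libraries at 21963, 30499 and 25965 FPKM and in KO embryos 1 and 3 at 12074 and 14555. Wtap, a subunit of the RNA methyltransferase complex, led in control embryo 1 at 24385 and in KO embryo 2 at 8920.2, and the oocyte gene Omt2b led in control embryo 2 at 27071. The RNA component of RNase MRP, Rmrp, led in all 4 ES cell libraries at 24780 to 32506 FPKM.

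The first pattern is the fall of Zscan4 genes in knockout embryos and knockdown ES cells. Reads moved between near-identical members would leave the family sum in place, but within embryos and within ES cells the lowest control sum was at least 4.28 times the highest KO embryo or KD ESC sum, respectively. Under TPM, median-of-ratios and quantile scaling in the 3 comparisons with controls the mean log2 fold change nearest to 0 was −2.15, which argues against scaling as well. Another stage of the embryos stays open, since no stage is given and the maternal oocyte list fell too (mean −1.32). That could not act in ES cells, where the sum was 9.70 times higher in the controls, so a hypothesis is that lower Dcaf11 goes with lower Zscan4, but 2 libraries against 2 cannot separate this from a difference between cultures. In embryos loss of Dcaf11 and stage cannot be told apart.

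The second pattern is the rise of ribosomal protein, oxidative phosphorylation and proteasome genes in KO arrest against control embryos. After the trend with gene length was removed the 3 lists kept at least 69.8% of their mean log2 fold change (2.55, 2.07 and 2.11 left), and with median-of-ratios or quantile scaling at least 79.6%, so neither length nor a few abundant genes accounts for the whole. Depth stays open in part: in 2 of the 3 embryo groups the deepest library was not the lowest in these lists, which a random order often gives, and every KO arrest library (0.373 to 0.659) was shallower than both controls (2.01 and 1.22). Libraries of similar depth still differed in the mean of the 3 lists. KO embryo 1 (0.585) stood at 5.15, and KO arrest 2 and 3 (0.523 and 0.659) at 6.58 and 6.70. KO embryo 3 (1.32) stood at 5.13 and control embryo 2 (1.22) at 3.71. The deepest library, control embryo 1, was the lowest (3.06). Depth alone thus does not order these libraries, but no KO arrest library matched a control in depth. The arrest that the titles name and a stage difference stay open as untested hypotheses, and the KO arrest libraries may also have been made apart from the others, which the labels do not say.

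The third pattern is the presence of blood and connective tissue transcripts in control and KO embryos. S100a9 and Lyz2 were listed at 0 in every KO arrest library but not in control or KO embryos. For these genes the values are not a floor common to all libraries. Of 20 bone marrow transcripts 1 reached 1 FPKM in every KO arrest library. That count tests little, because several members had been seen before the list was written and every KO arrest library was shallower than both controls. KO embryo 1 (relative depth 0.585) was shallower than KO arrest 3 (0.659), yet 12 members reached 1 FPKM in it against 2. This compares single libraries only. RNA from other cells may be a source, but the share of that list cannot decide this, since members seen before it was written, such as S100a9 and Lyz2, contribute to it. Of the list 30% reached 1 FPKM in every control and KO embryo library, between the bounds of over 50% and under 25% set before the count, with S100a9 at up to 245 FPKM and Lyz2 at up to 35.9, whereas Mpo stayed at or below 1.37. Of the connective tissue list 9 of 12 members did so, with Col1a2 at up to 35.5 FPKM, against 1 in every KO arrest and 5 in every ES cell library, and of the 10 liver, 10 muscle and 10 brain transcripts 0, 0 and 0 did, against 0, 1 and 1 in every KO arrest library. No biological explanation was tested, and embryonic expression cannot be told apart from RNA of other cells.

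The 1012 genes called between KO arrest and KO embryos were set against other splits of the same 6 libraries into 3 and 3. Of the 10 splits, 1 called as many, the real one, and the highest of the others called 3. With 10 splits the share cannot fall under 0.05.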
